A study of Mus musculus with 2 samples.

How the data were processed

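Single-cell RNA counts were deposited for 2 libraries of mouse heart, each from the hypertrophied left ventricles of 3 hearts mixed into 1 sample, collected 6 weeks after transverse aortic constriction (TAC). TAC is a surgical narrowing of the aorta that loads the left ventricle with pressure. One library is labelled wild-type and the other p53 knockout, so each group has 1 library and the spread between animals cannot be measured. The values are whole-number counts of unique molecular identifiers (UMIs) per gene and barcode, and per the submitters' processing notes the authors used Cell Ranger, Seurat and the mouse build mm10, with versions not given in the sources used here. The labels' protocols name a 10x Chromium 3' kit, whereas the barcodes in the deposited count files are written as 3 blocks of 9 bases, a form that differs from that kit's; which kit made the libraries was left open. The labels' protocols also speak of extracting total RNA with a kit, and do not say whether cells or nuclei were loaded. They give the cell type as cardiomyocytes, while the counts hold cells of many classes.

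The files hold 32589 gene identifiers, of which 32445 matched GENCODE vM21 on the same build; positions are from that annotation. The lowest total per barcode was 500 UMIs in both libraries. Cells were kept with at least 200 detected genes and at most 50% mitochondrial UMIs. Scrublet scores were computed per library with scanpy 1.11.5 at an expected rate of 0.08. Its automatic threshold marked 0 barcodes in either library, under the planned minimum of 0.5%, so the planned fallback removed the 8% of cells with the highest scores, 1284 from the library labelled wild-type and 808 from the other. The fallback removes a fixed share and does not show that these cells were doublets. It left 14763 and 9298 cells.

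Both libraries were clustered together without integration, on 2000 variable genes chosen per library and merged, leaving out mitochondrial, ribosomal, haemoglobin and sex-linked genes. Counts were scaled to 10000 per cell and log transformed, and 30 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2) at resolution 1 were used. Clusters were called "X-like" from 19 fixed marker lists, with at least 3 markers of the class at 2-fold or more over the remaining cells. A cluster stayed unnamed where its 10 leading genes held more markers of another class. The markers were fixed, whereas these naming thresholds were set after the counts had been opened: a marker detected in at least 5% of the cluster's cells, a mean log2 fold of at least 0.5 over the class's markers, and 20 CPM added to both sides of a fold. One departure from the fixed markers was also made after the data were seen: haemoglobin genes were left out of naming. With them, cluster 16 had been called erythroid-like and cluster 21 had stayed unnamed. Without them, cluster 16 stayed unnamed; it held 0.0135% of cells in the library labelled wild-type and 3.47% in the other. Cluster 21 then became endocardial-like, and it held 0.400% and 0.710%.

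Within each class UMIs were summed per library and given as CPM of nuclear-encoded UMIs. Log2 ratios are of the library labelled p53 knockout over the library labelled wild-type, with 0.5 UMI added to each sum. Intervals are 95% and exact: Poisson for summed counts, Clopper-Pearson binomial for shares, and conditional binomial for ratios. All of these cover counting error only, not differences between animals, dissections or library preparations. The interval of a list median is instead taken from the ordered ratios of the list's genes. It covers the spread between those genes. With 1 library per group no test across samples was possible, and no p-value or number of changed genes is given. A gene with 0 UMIs in a library was compared with a floor of 3 counts in that library and class, and a share of 0 cells is given with the share that 3 cells would be. The exact interval of a count of 0 reaches above this floor, so a fold against it is not a lower bound.

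The lists of genes, the markers, the rule for named genes and the alternative settings were fixed before the data were examined. A gene was eligible in a class with at least 50 cells per library if it had at least 100 UMIs in at least 1 library. Its class CPM in the higher library also had to be at least 0.5 times its CPM over all kept cells, which limits genes carried by free RNA. Mitochondrial, ribosomal protein, haemoglobin, Xist, Tsix and Y-linked genes and unnamed gene models were left out. The 12 highest and 12 lowest genes were named in cardiomyocyte-like cells and the 5 highest and 5 lowest in the 3 other classes with the most cells. Some genes that this rule takes are not reported here. Trp53 was named too, and of each list up to 4 members with the most UMIs plus the member with the most positive and the most negative ratio. For 31 gene lists the median log2 ratio was taken over members with at least 20 UMIs over both libraries, with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these 2 libraries and is not a test between genotypes. Shares of cells with a UMI were taken after thinning each cell to 500 UMIs, which left out 0 cells because no kept cell was shallower.

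The alternatives changed 1 choice at a time. They covered at least 500 genes per cell, a mitochondrial limit of 20% or none, doublets kept, resolutions 0.5 and 2, and a class per cell from marker scores. They also covered CPM of all genes, median of ratios, the mean of per-cell CPM, list members with at least 100 UMIs, and thinning to 1000 UMIs or none. A further 4 subsets of cardiomyocyte-like cells, and class shares among cells that are not cardiomyocyte-like, were added after the data were seen. A value was taken as moved where it left its own 95% interval, or, for list medians over under 6 members, where it shifted by more than 0.5; this tolerance was set after the data were seen. It was taken as reversed where the interval lay on one side of 0 and the alternative on the other.

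The ratio and the list percentile were tested on simulated counts, drawn for the 9316 genes of cardiomyocyte-like cells from their means and library sizes. Of 50 genes raised by 1 on the log2 scale, 100% had the right direction and the median ratio was 0.98. The intervals held the true ratio for 95.9% of genes, and a list raised by 1 stood at percentile 100. Both libraries were drawn as Poisson counts from 1 shared profile, so these outcomes follow from the setup and check the computation only. The simulated counts hold no spread between animals, no free RNA and no change in the mix of cells. A list with no change stood at percentile 64.5 there, and at 13.1, 97.3 and 71.9 in counts simulated in the same way for fibroblast-like, vascular endothelial-like and endocardial-like cells. A single high percentile can therefore arise without any change. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.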

Results

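The data are UMI counts of single cells from the pressure-loaded left ventricle of mice 6 weeks after TAC, in 1 library labelled wild-type and 1 labelled p53 knockout. The design asks how loss of p53, the transcription factor encoded by Trp53, alters the hypertrophied heart. The library labelled wild-type held 16060 barcodes and 18897913 UMIs, and the library labelled p53 knockout held 10118 barcodes and 20918824 UMIs. After filtering, 14763 and 9298 cells remained, with medians of 937 and 1569 UMIs and of 602 and 929 genes per cell. The median mitochondrial share was 3.04% and 2.82%. The nuclear transcript Malat1 took 5.10% and 3.52% of nuclear-encoded UMIs. There are no replicate libraries, and all intervals printed with levels, shares and ratios of genes cover counting error only.

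Over all kept cells, Trp53 was not lower in the library labelled p53 knockout. Trp53 (ENSMUSG00000059552; chromosome 11, 69580359 to 69591873, mm10) had 38.8 CPM (interval 35.9 to 41.9) over all kept cells of the library labelled wild-type and 54.8 CPM (51.4 to 58.2) in the other, a log2 ratio of 0.50 (0.35 to 0.64). In cardiomyocyte-like cells the level was 28.4 CPM (24.3 to 32.9) against 27.2 CPM (20.8 to 34.9), a log2 ratio of -0.06 (-0.51 to 0.37). Subsets of these cells chosen after the data were seen went both ways, each with an interval that holds 0. In those of 500 to 1500 UMIs the level was 31.6 and 16.2 CPM from 92 and 5 UMIs, a log2 ratio of -0.84 (-2.62 to 0.31). In the cluster rich in mitochondrial RNA it was 19.0 and 32.3 CPM from 15 and 18 UMIs, a log2 ratio of 0.76 (-0.31 to 1.86). The ratio was -0.21 without that cluster and -0.19 without cells that hold atrial genes. Endocardial-like cells had 38.2 and 68.9 CPM, a log2 ratio of 0.84 (0.46 to 1.25). The intervals of the other large classes held 0: fibroblast-like cells had 48.2 and 58.5 CPM (0.28), vascular endothelial-like cells 44.4 and 50.2 CPM (0.18) and macrophage-like cells 61.1 and 60.9 CPM (-0.01). The ratio over all kept cells thus lay above that of 4 of the 5 largest classes. Cardiomyocyte-like cells, which had the lowest level of the 5 in both libraries, were 32.4% and 9.30% of kept cells. After thinning to 500 UMIs, 1.77% of cells (1.56 to 1.99) and 2.24% (1.95 to 2.56) had a Trp53 UMI; without thinning the shares were 3.68% and 8.38%. In cardiomyocyte-like cells the thinned shares were 1.46% (1.14 to 1.85) and 0.925% (0.400 to 1.81), and without thinning they were 3.33% and 5.09%. No class that should lack Trp53 was available as a background. The labels do not name the deleted exons, so 3' reads may lie outside the deletion, in which case this level checks nothing. Over all kept cells the label therefore has no support from the gene's own counts, and in cardiomyocyte-like cells the intervals of the ratio hold 0. Every direction below is one between the library labelled p53 knockout and the library labelled wild-type.

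Genes known to respond to p53 went both ways. Of the 34 measured members of the p53 target list in cardiomyocyte-like cells, 16 were higher and 18 lower in the library labelled p53 knockout, with a median log2 ratio of -0.06 (percentile 94.0 of random lists). Perp was at 25.4 and 84.6 CPM, Fas, a death receptor, at 39.9 and 16.9 CPM, and Mdm2, the ubiquitin ligase that limits p53, at 77.6 and 62.3 CPM. The list's median was 0.20 (percentile 99.6) in fibroblast-like, 0.00079 (72.7) in vascular endothelial-like, 0.01 (82.3) in endocardial-like and 0.42 (99.9) in macrophage-like cells. Cdkn1a, the p21 cell cycle inhibitor and a direct p53 target, was higher in the library labelled p53 knockout over all kept cells (22.1 and 63.5 CPM). It reached 43.6 and 148 CPM in vascular endothelial-like cells. After thinning, 1.06% and 2.86% of cells had a Cdkn1a UMI, against 1.96% and 8.23% without thinning. No class was taken to lack Cdkn1a, so these shares have no background level. Ccng1, another target, was lower (94.6 and 52.0 CPM over all kept cells) but similar in cardiomyocyte-like cells (151 and 154 CPM). These cells had its highest level and a smaller share in the library labelled p53 knockout, which lowers the level over all kept cells. Within fibroblast-like, vascular endothelial-like, endocardial-like and macrophage-like cells its log2 ratios were -0.70, -0.78, -0.91 and -0.86, each with an interval below 0.

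The libraries also differed in sex-linked RNA. Xist, which is transcribed from the inactive X chromosome of females, had 2.37 CPM in the library labelled wild-type and 930 CPM in the other. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty together had 538 and 7.34 CPM. The difference was present in each of the 5 largest classes: the median of the sex-linked list lay between -5.67 in cardiomyocyte-like and -8.11 in endocardial-like cells. With members that had 0 UMIs set to the 3-count floor, these medians were -5.53 and -6.53, and that of macrophage-like cells went from -7.998 to -5.41. Sex and genotype are therefore not separable in any comparison between these libraries.

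**Figure D1:**
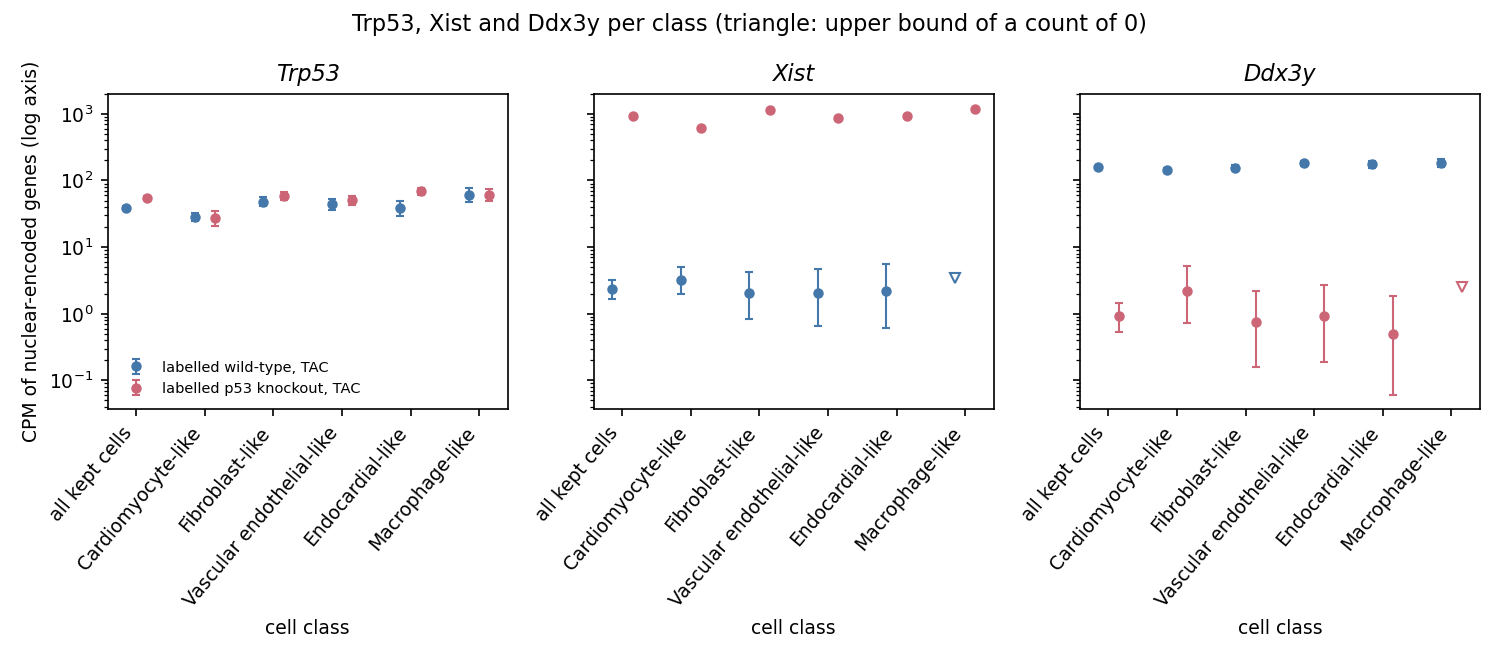
CPM of nuclear-encoded genes (log axis) for Trp53, Xist and Ddx3y over all kept cells and in the 5 largest classes, with points for each library and bars for exact 95% Poisson intervals; an open triangle marks the upper bound where the count was 0. Trp53 is at 38.8 and 54.8 CPM over all kept cells, while Xist is at 2.37 and 930 CPM and Ddx3y at 159 and 0.918 CPM.

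Cardiomyocyte-like cells made up a smaller share of the library labelled p53 knockout. Cardiomyocyte-like cells were 32.4% of kept cells (31.6 to 33.1) in the library labelled wild-type and 9.30% (8.72 to 9.91) in the other, 3.48 times lower. Endocardial-like cells were 11.1% and 17.7%, and macrophage-like cells 6.97% and 10.0%. Fibroblast-like cells were 21.2% and 21.1%, and vascular endothelial-like cells 18.9% and 20.96%. Pericyte-like cells were 5.16% and 2.54%. Shares sum to 100%, so the smaller cardiomyocyte-like share by itself raises every other class 1.34-fold. Among cells that are not cardiomyocyte-like, a total chosen after the data were seen, endocardial-like cells were 16.4% (15.6 to 17.1) and 19.5% (18.7 to 20.4), and macrophage-like cells 10.3% (9.72 to 10.9) and 11.1% (10.4 to 11.8). Fibroblast-like cells were then 31.3% and 23.2%, vascular endothelial-like cells 27.9% and 23.1%, and pericyte-like cells 7.63% and 2.80%. Over all kept cells, the macrophage-like difference, a log2 ratio of 0.53, was 0.12 with at least 500 genes per cell and with resolution 2. Shares depend on dissociation, on the 500-UMI minimum and on the unequal depth of the libraries.

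Smaller classes were mostly more frequent in the library labelled p53 knockout. Lymphatic endothelial-like cells were 1.42% and 3.40%, mesothelial-like cells 1.22% and 3.03%, B-like cells 0.562% and 2.54%, and T or NK-like cells 0.284% and 1.49%. Smooth muscle-like cells were 0.366% and 1.98%, monocyte or dendritic-like cells 0.135% and 0.731%, and adipocyte-like cells 0.210% and 0.613%. Neutrophil-like cells were 0 of 14763 cells against 1.04%, which is 51.3-fold above the 0.0203% that 3 cells would be. The exact interval of that share of 0 reached 0.0250%. Schwann-like cells numbered 26 and 6. Among cells that are not cardiomyocyte-like, the first 7 of these classes had log2 ratios of 0.84 (lymphatic endothelial-like) to 2.01 (smooth muscle-like).

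**Figure D2:**
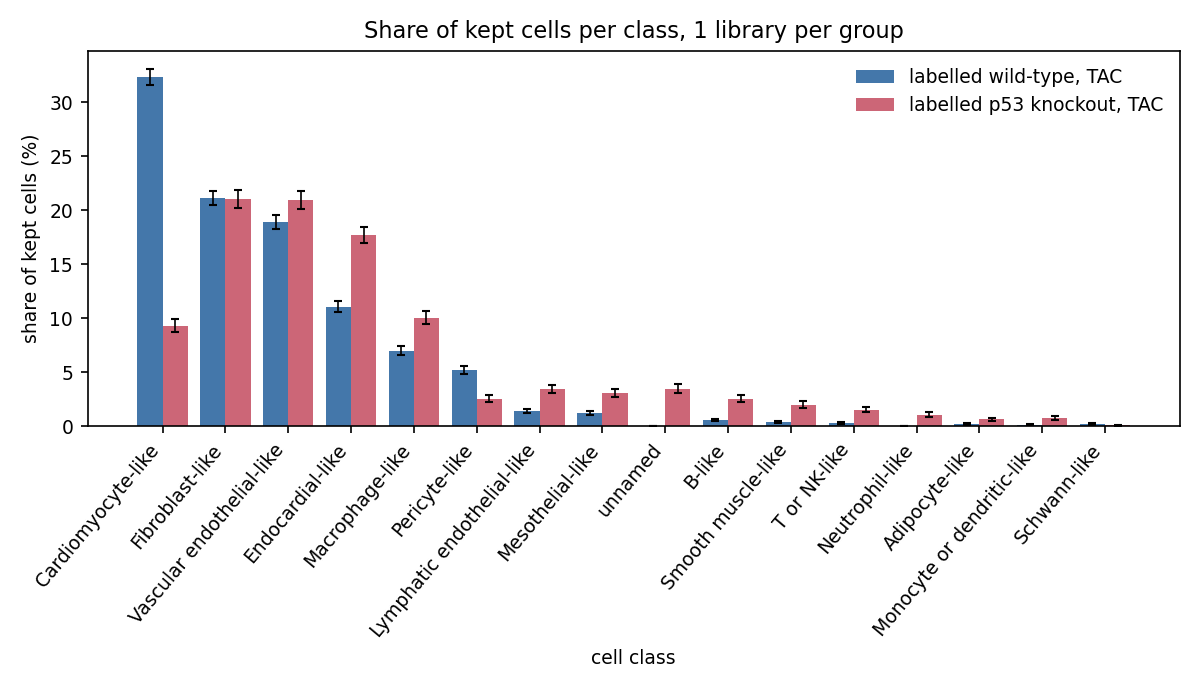
Share of kept cells (%) in each class for the 2 libraries, with bars for shares and error bars for exact 95% binomial intervals. Cardiomyocyte-like cells take 32.4% in the library labelled wild-type and 9.30% in the library labelled p53 knockout, while fibroblast-like cells take 21.2% and 21.1%.

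Different clusters held the same class in the 2 libraries. Of 4779 cardiomyocyte-like cells in the library labelled wild-type, 2429 were in cluster 1, 1475 in cluster 6 and 822 in cluster 9; of 865 in the other, 434 were in cluster 13 and 318 in cluster 9. Cluster 9 had a median mitochondrial share of 20.3% and was led by genes that include Nppa, Nppb, Acta1 and Ankrd1, and cluster 13 was led by genes that include Myh7. Fibroblast-like cells were mostly in cluster 0 (3002 cells) in one library and cluster 4 (1791 cells) in the other, and endocardial-like cells in cluster 3 (1561) and cluster 8 (1220). Vascular endothelial-like cells were mostly in cluster 2 (2020) in one and in clusters 7 (905) and 10 (682) in the other. Macrophage-like cells shared cluster 5 (1020 and 572), while cluster 15 held 9 and 362. A cluster that comes mostly from 1 library may reflect that library and not a cell type.

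In cardiomyocyte-like cells, fetal and stress genes of hypertrophy were higher in the library labelled p53 knockout. All 19 measured members of the list were higher, 14 of them at least 2-fold, with a median log2 ratio of 2.01 (percentile 100). Nppa (ENSMUSG00000041616; chromosome 4, 148000722 to 148002079), which encodes atrial natriuretic peptide, had 43.9 CPM and 5706 CPM, a log2 ratio of 7.02 (6.85 to 7.20). Without the cluster rich in mitochondrial RNA, a subset chosen after the data were seen, Nppa had 15.8 and 698 CPM, a log2 ratio of 5.46, and in that cluster alone 236 and 20875 CPM; the list's median was 1.53 without it. Nppb, which encodes B-type natriuretic peptide, had 81.9 and 1527 CPM, and Acta1, skeletal alpha-actin, 69.9 and 1072 CPM. Myh7, the beta myosin heavy chain, had 188 and 2167 CPM, Ankrd1 308 and 3128 CPM, Xirp2 613 and 1813 CPM, and Tuba8 44.6 and 51.2 CPM. Myh6, the adult alpha myosin heavy chain, was at 12952 and 12145 CPM. After thinning, 1.21% and 31.4% of cardiomyocyte-like cells had an Nppa UMI (2.20% and 54.2% without thinning). The share in B-like cells, which should lack the gene, was 0% (0 of 83 cells, where 3 cells would be 3.61%) and 8.90%, at median depths of 884 and 1126 UMIs. The median depths of cardiomyocyte-like cells were 995 and 1759 UMIs.

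The other genes with the highest ratios among those eligible for naming included atrial genes. Sln, a regulator of the sarcoplasmic calcium pump, had 0.486 and 110 CPM from 3 and 246 UMIs, a log2 ratio of 7.60 (6.25 to 10.10). Myl7, an atrial myosin light chain, had 1.13 and 223 CPM, and Myl4, another one, 6.48 and 530 CPM. Cells with a UMI of Myl7, Sln, Bmp10 or Sbk2 were 0.523% and 8.44% of cardiomyocyte-like cells. In the library labelled p53 knockout they held 65.0% of Nppa UMIs, 94.2% of Myl4 UMIs and 2.57% of Myh7 UMIs. They also held 33.0% of Nppb, 23.4% of Ankrd1 and 3.37% of Acta1 UMIs there. Without them, Nppa had a log2 ratio of 5.70, Nppb of 3.78, Ankrd1 of 3.09, Acta1 of 4.02 and Myh7 of 3.62. Nmrk2, an enzyme of NAD synthesis, had 8.10 and 125 CPM, Cyfip2 8.43 and 103 CPM, Ndrg4 22.2 and 258 CPM, Dkk3 4.05 and 45.4 CPM, and Kctd16 20.4 and 216 CPM. Without the cluster rich in mitochondrial RNA the log2 ratios of Sln, Myl7, Myl4 and Dkk3 were 3.99, 3.51, 3.08 and 1.89, against 7.60, 7.52, 6.34 and 3.47 with it. Without cells that hold atrial genes that of Dkk3 was 1.71. Over all kept cells of the library labelled p53 knockout Dkk3 had 70.7 CPM, above its 45.4 CPM in this class.

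The lowest ratios in cardiomyocyte-like cells among genes eligible for naming included metabolic and transport genes. Slc15a2 (ENSMUSG00000022899; chromosome 16, 36750177 to 36784962), a peptide transporter, had 157 and 6.68 CPM, and Aqp7, a glycerol channel, 20.1 and 1.34 CPM, a log2 ratio of -3.70 (-6.21 to -2.33) that rests on 3 UMIs in the library labelled p53 knockout. Pfkfb1 had 123 and 16.9 CPM, Slc40a1, the iron exporter ferroportin, 25.1 and 2.67 CPM, and Nr4a2, a nuclear receptor, 72.3 and 8.01 CPM. Cstdc2 and Cxxc4, also with 3 UMIs there, had log2 ratios of -3.997 (-6.51 to -2.64) and -3.39 (-5.90 to -2.01). Ano5, Lrrtm3, Cngb3 and Amacr had log2 ratios of -3.04, -2.88, -2.86 and -2.82. Over all kept cells of the library labelled wild-type, Slc15a2, Aqp7 and Cxxc4 had 199, 30.2 and 23.8 CPM. That is above their levels in this class (157, 20.1 and 16.2 CPM), so free RNA or other cells as a source was not excluded. Lrrtm3 was about level, at 28.0 and 27.7 CPM. Pfkfb1, Slc40a1, Nr4a2, Cstdc2, Ano5, Cngb3 and Amacr had higher levels in this class. The median over genes with at least 100 UMIs in a library was -0.23 in this class, and median-of-ratios scaling shifted all ratios in it by 0.15, and those in endocardial-like cells by 0.11.

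**Figure D3:**
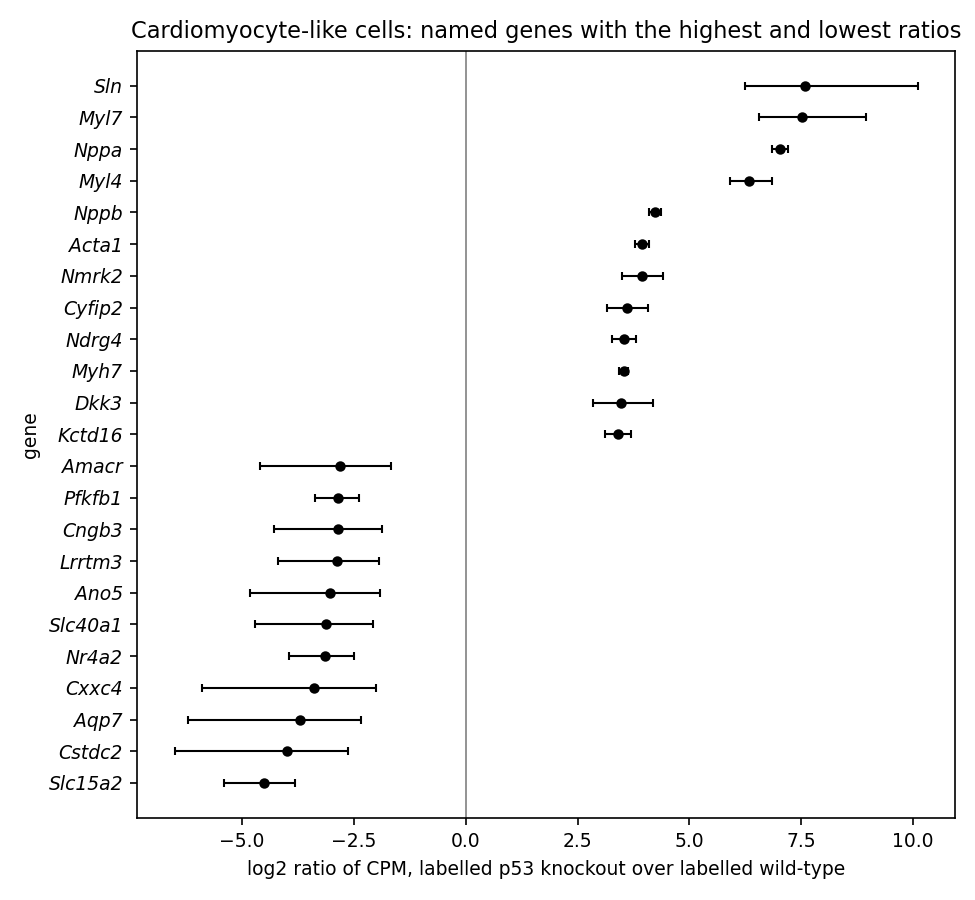
Log2 ratio of CPM, library labelled p53 knockout over library labelled wild-type, for the named genes with the highest and lowest ratios in cardiomyocyte-like cells, with points for ratios and bars for exact 95% counting intervals. Ratios run from 7.60 for Sln to -4.51 for Slc15a2.

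Energy metabolism lists in cardiomyocyte-like cells moved apart. Of 31 fatty acid oxidation genes, 23 were lower in the library labelled p53 knockout, with a median of -0.43 (percentile 0.05); Ucp3, a mitochondrial carrier, had 217 and 65.9 CPM, Cd36, a fatty acid transporter, 2005 and 1674 CPM, and Fabp3 1335 and 2122 CPM. Of 23 genes of glycolysis and glucose use, 19 were higher, with a median of 0.77 (percentile 100). Pfkp, a phosphofructokinase, had 43.9 and 169 CPM, Aldoa 284 and 560 CPM, and Ldhb 577 and 308 CPM. Without cluster 9, the cluster rich in mitochondrial RNA, these medians were -0.94 and 0.22, a subset added after the data were seen. The medians of nuclear oxidative phosphorylation (0.14), mitochondrially encoded genes (0.50), cytosolic ribosomal proteins (0.38) and immediate early and dissociation stress genes (0.34) became -0.84, -0.97, -0.55 and -0.11 without it.

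Contraction genes included higher and lower members. Of 21 adult sarcomere genes 15 were higher, with a median of 0.56; Actn2, alpha-actinin, had 1114 and 2635 CPM, Ttn, titin, 21378 and 17006 CPM, and Tnnt2 7367 and 5801 CPM. Of 24 calcium handling and channel genes 15 were higher, with a median of 0.20, including Slc8a1, the sodium-calcium exchanger, at 3120 and 6787 CPM and Kcnd2, a potassium channel, at 1006 and 537 CPM. Of 21 hypoxia and angiogenesis genes 14 were higher, with a median of 0.54; Vegfa had 1115 and 1619 CPM and Angptl4 24.5 and 4.01 CPM. The medians of the remaining lists in this class were 0.74 for extracellular matrix and fibrosis, 0.67 for senescence and its secretome and 0.29 for endoplasmic reticulum stress. Without the cluster rich in mitochondrial RNA, a subset chosen after the data were seen, the first 2 were 0.405 and 0.032. Medians of ferroptosis and iron (0.17), oxidative stress defence (0.02), the TCA cycle (0.04), apoptosis (-0.00028), autophagy (-0.05) and mitochondrial biogenesis and dynamics (-0.0042) lay nearer to 0; without that cluster the TCA cycle was -0.44 and oxidative stress defence -0.56. Inflammatory cytokines and chemokines (0.19), antigen presentation (0.24), interferon response (-0.16), cell cycle S (-0.29), cell cycle G2M (0.45) and nuclear RNA (0.11) completed the set. Blood RNA, led by the haemoglobin gene Hbb-bs (242 and 1439 CPM), had a median of 2.54 in these cells, which should lack it. The macrophage lists had medians of -1.36 (resident) and 2.02 (monocyte-derived) there. Of the 13 genes of the monocyte-derived list 7 were measured, led by Cd9, Fn1, Thbs1 and Lgals3. Fn1 and Thbs1 are also in the matrix list.

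**Figure D4:**
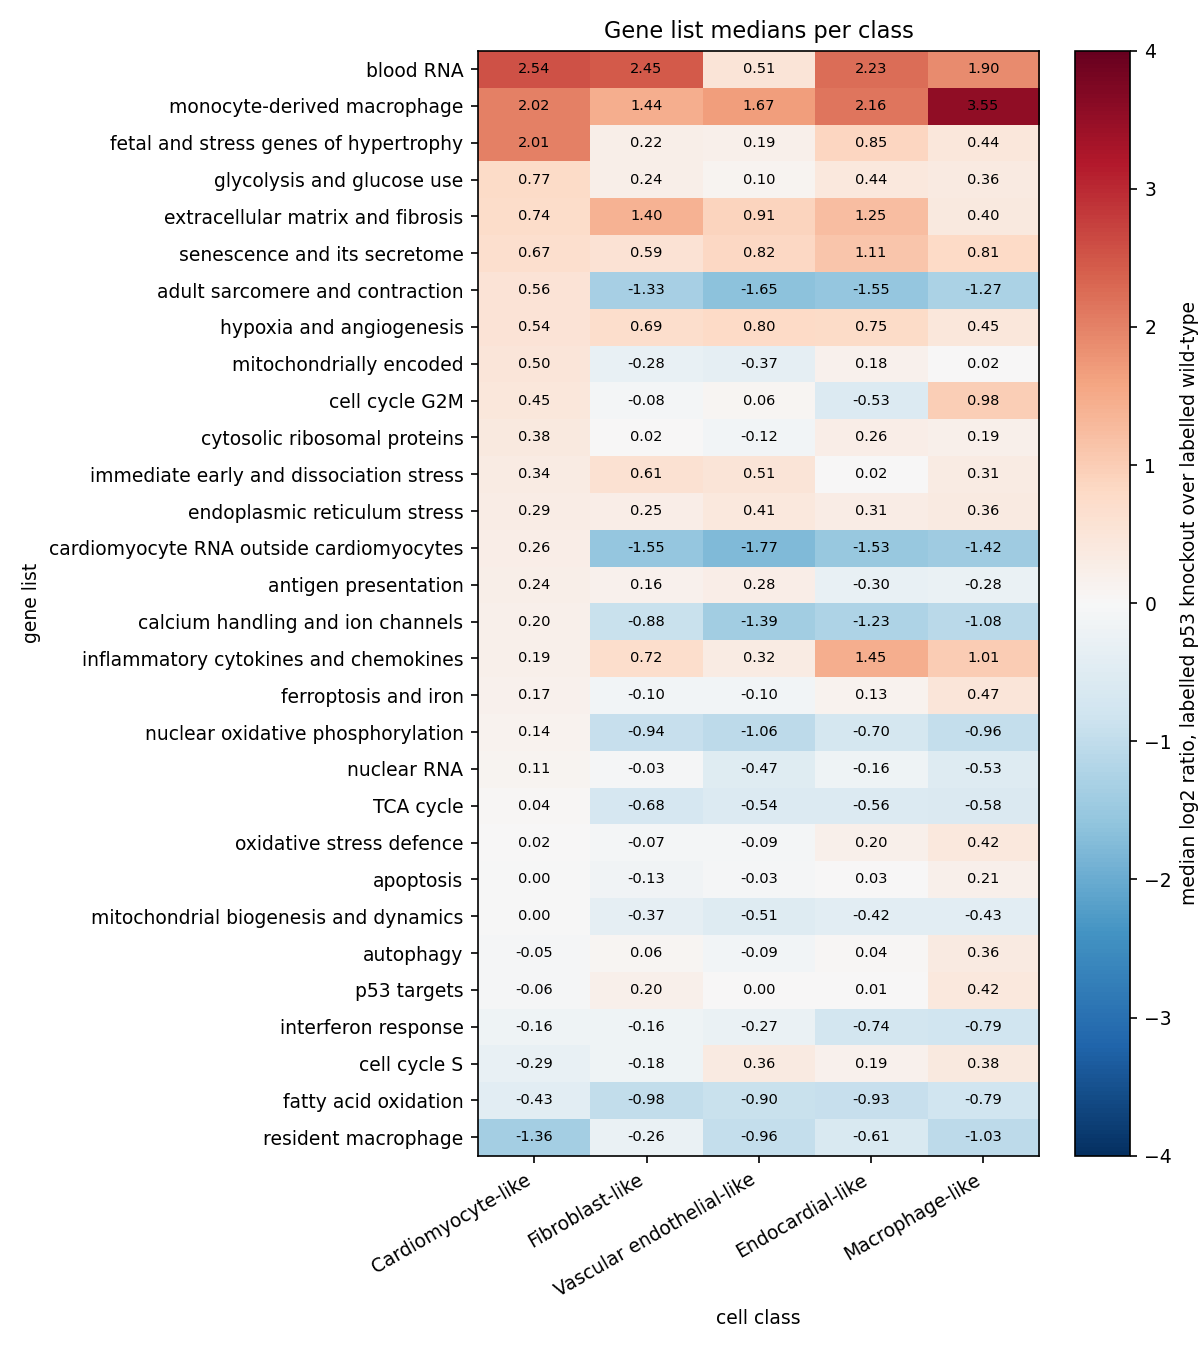
Median log2 ratio, library labelled p53 knockout over library labelled wild-type, of each gene list (rows) in the 5 largest classes (columns), with colour and printed value for the median. The fetal and stress list stands at 2.01 in cardiomyocyte-like cells, and the list of cardiomyocyte RNA lies between -1.42 and -1.77 in the other 4 classes.

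Cardiomyocyte RNA outside cardiomyocytes differed between the libraries. Its 10 marker genes took 0.663% of nuclear-encoded UMIs, as the median of the other classes, in the library labelled wild-type and 0.180% in the other. Myh6 in fibroblast-like cells had 1632 and 239 CPM. Lists of genes abundant in cardiomyocytes moved with it: in fibroblast-like, vascular endothelial-like, endocardial-like and macrophage-like cells the adult sarcomere medians were -1.33, -1.65, -1.55 and -1.27. Nppa went the other way, with 16.4 and 245 CPM in fibroblast-like cells.

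Fibroblast-like cells of the library labelled p53 knockout held more matrix RNA. Of 38 extracellular matrix and fibrosis genes 37 were higher, 24 of them at least 2-fold, with a median of 1.40 (percentile 100). Comp, a cartilage matrix protein, had 10.2 and 651 CPM, Ccn2, connective tissue growth factor, 206 and 2360 CPM, Col8a1 1100 and 2842 CPM, Col3a1 907 and 1898 CPM, and Dcn, decorin, 5650 and 4833 CPM. Spp1, osteopontin, had 0 UMIs and 92.6 CPM, 106-fold above the floor of 3 counts. The interval of its log2 ratio began at 6.42. Spp1 and Ccn2 were at least 4-fold higher in each of the 5 largest classes. Il6, a cytokine, had 1.46 and 89.3 CPM, Dio2, the deiodinase that activates thyroid hormone, 1.75 and 136 CPM, and Thbs4, a thrombospondin, 2.63 and 137 CPM. Among genes eligible for naming, the lowest ratios were those of Cnmd (31.6 and 0.509 CPM, a log2 ratio of -5.64 with an interval of -9.02 to -4.07), Slc15a2 (107 and 2.80 CPM), Tpm3-rs7 (31.3 and 1.27 CPM), the chemokine gene Ccl11 (59.3 and 2.80 CPM) and the collagen gene Col6a6 (143 and 10.7 CPM). Hypoxia and angiogenesis had a median of 0.69, senescence and its secretome 0.59, and immediate early and dissociation stress 0.61. The monocyte-derived macrophage list, which shares Fn1 and Thbs1 with the matrix list, had a median of 1.44 in the same cells. Blood RNA had a median of 2.45, and of 0.57 to 1.93 under the settings that moved it.

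In vascular endothelial-like cells, the 5 highest ratios among genes eligible for naming were as follows. Npnt, nephronectin, had 1.63 and 41.3 CPM, Bdkrb2, a bradykinin receptor, 1.63 and 38.8 CPM, Adamtsl1 22.8 and 467 CPM, Adamts8 2.04 and 41.6 CPM, and Inhba, a subunit of activin, 5.29 and 83.2 CPM. Gabrb2, which encodes a subunit of a neurotransmitter receptor, was lower, with 212 and 0.924 CPM, a log2 ratio of -7.62 (-10.12 to -6.29). Also lower were Slc15a2 (371 and 5.85 CPM), Tpm3-rs7 (70.0 and 4.31 CPM) and Tspan8 (48.0 and 3.08 CPM). Gabrb2, Slc15a2 and Tpm3-rs7 were at least 4-fold lower in each of the 5 largest classes, not in this class alone. Of 21 hypoxia and angiogenesis genes 18 were higher, with a median of 0.80 (percentile 100); Egln3, an oxygen-sensing hydroxylase, had 12.2 and 104 CPM and Vegfb 47.2 and 13.9 CPM. The matrix list had a median of 0.91, with Col4a1 at 382 and 1041 CPM, and Igfbp5 had 223 and 2272 CPM. Adamtsl1 and Igfbp5 were among the leading genes of cluster 10. That cluster held 321 of the 2790 cells of this class in the library labelled wild-type and 682 of 1949 in the other. Inhba, Adamts8 and Igfbp5 were among the leading genes of cluster 21, which was named endocardial-like. Whether the mix of clusters carries these ratios was not tested. The monocyte-derived macrophage list had a median of 1.67 and blood RNA 0.51 in these cells. Both depended on the settings: the former was 4.06 by marker scores, and blood RNA was 1.32 to 1.81 under the settings that moved it.

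Endocardial-like cells of the library labelled p53 knockout held more RNA of inflammatory and matrix genes. Fgf23, a hormone of phosphate balance, had 0.554 and 228 CPM from 1 and 903 UMIs, a log2 ratio of 8.10 (6.20 to 13.99). Olr1, a receptor for oxidised lipoprotein, had 0.554 and 111 CPM from 1 and 440 UMIs, a log2 ratio of 7.06 (5.16 to 12.95). Il6 and P4ha3, a collagen prolyl hydroxylase, had 0 UMIs in the library labelled wild-type and were 27.2-fold and 18.8-fold above the 3-count floor. The intervals of their log2 ratios began at 4.45 and 3.91. Of 16 inflammatory cytokine and chemokine genes 14 were higher, with a median of 1.45 (percentile 100), including Ccl2 at 10.5 and 174 CPM, while Ptgs2 had 168 and 75.4 CPM. Of 38 matrix genes 35 were higher, with a median of 1.25; Fn1, fibronectin, had 273 and 1615 CPM. Lists of other cell types were higher in the same cells: all 8 measured genes of the monocyte-derived macrophage list, with a median of 2.16, and all 5 of blood RNA, with a median of 2.23. The former shares Fn1 and Thbs1 with the matrix list and Spp1 and Il1b with the inflammatory one. Of the genes eligible for naming, the lowest ratios were those of Slc15a2 (120 and 4.54 CPM), Gstp2 (69.3 and 3.78 CPM), Tpm3-rs7 (62.6 and 4.04 CPM), Nmnat1 (93.7 and 7.82 CPM) and Igfbp6 (166 and 21.7 CPM).

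Macrophage-like cells held less RNA of the resident list and more of the monocyte-derived list in the library labelled p53 knockout. Of 11 resident macrophage genes 10 were lower, with a median of -1.03 (percentile 0), including Timd4 at 203 and 29.8 CPM, Lyve1 at 646 and 222 CPM and Mrc1 at 2658 and 1541 CPM. All 12 measured genes of the monocyte-derived list were higher, with a median of 3.55 (percentile 100), including Thbs1 at 9.26 and 496 CPM, Lgals3 at 34.3 and 344 CPM and Ccr2 at 149 and 298 CPM. Of 24 inflammatory genes 17 were higher, with Spp1 at 13.9 and 253 CPM. Of 21 interferon response genes 16 were lower, with a median of -0.79 (percentile 0), and Ifi203 had 589 and 184 CPM. Cluster 15, led by genes that include Gpnmb, Arg1 and Mmp12, held 362 of these 934 cells and 9 of 1029. Blood RNA had a median of 1.90 in macrophage-like cells.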

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

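All tests of explanations in this part were chosen after the patterns were seen; for Myl4 alone the bounds were written before its value without cells that hold atrial genes was seen.

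The first entry is a signal in cells outside every named class. Among the compared values, they enter those over all kept cells and the totals behind class shares. Those totals include that of cells that are not cardiomyocyte-like. An unnamed cluster held 3.47% of kept cells in the library labelled p53 knockout, 323 cells, and 2 cells of the other library. The 323 cells were shallow, with a median of 698 UMIs against 1569 over all kept cells of that library. Whether they form a cell type was not tested. Its leading genes were Chl1, Gpc5, Nrg3, Lrp1b and Dpp10.

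The second is a difference in direction between classes, which was not tested. The median log2 ratio of nuclear oxidative phosphorylation genes was 0.14 in cardiomyocyte-like cells, and -0.94 in fibroblast-like, -1.06 in vascular endothelial-like and -0.70 in endocardial-like cells. The value in cardiomyocyte-like cells did not hold without the cluster rich in mitochondrial RNA, where it was -0.84. The list of cardiomyocyte RNA had medians of -1.55, -1.77 and -1.53 in the other 3 classes.

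Cardiomyocyte-like cells of the library labelled p53 knockout held more RNA of the fetal and stress genes. Atrial cells could bring Nppa, but without cells that hold a UMI of Myl7, Sln, Bmp10 or Sbk2 the list's median was 2.03. This argues against the cells left out as the cause for the list as a whole. Atrial cells in which none of these genes was detected would remain, so the value does not cover them. For Myl4 the ratio went from 6.34 to 2.63, between the bounds, and atrial cells stay open for it. More cells rich in cytoplasmic RNA, or deeper cells, are argued against as whole causes by medians of 1.53 outside the cluster rich in mitochondrial RNA and 2.14 in cells of 500 to 1500 UMIs. Sex cannot be told apart from genotype, since Xist differed by 8.60 on the log2 scale, and the genotype itself and the strength of the aortic constriction stay open and untested.

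Over all kept cells Trp53 was not lower in the library labelled p53 knockout, with a log2 ratio of 0.50; of the 5 largest classes the interval lay above 0 in endocardial-like cells (0.84) and held 0 in the other 4. Cells of the other library mixed in are argued against, because Y-linked CPM was 1.36% of that in the library labelled wild-type. Exchanged labels stay open: the p53 target list had medians whose own median over the 5 largest classes was 0.009, over members that went both ways. Among random lists it stood at percentile 99.6 in fibroblast-like and 99.9 in macrophage-like cells, as an exchange would need, but at 94.0 in cardiomyocyte-like, 82.3 in endocardial-like and 72.7 in vascular endothelial-like cells. Reads from Trp53 exons outside the deletion might account for the level, which counts per gene cannot show, so the ratio of 0.50 leaves this open as well.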

How the results depend on the processing

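Cardiomyocyte subsets and shares of cells that are not cardiomyocyte-like were added after the data were seen; the others were planned. No paired analysis was possible because each group is 1 library of pooled hearts. Each result has 1 library per group, so these values show dependence on processing and nothing about variation between animals. The ratio of Trp53 over all kept cells stayed within its interval in 7 of 7 alternatives. In cardiomyocyte-like cells it went from -0.06 (-0.51 to 0.37) to -0.84 in those of 500 to 1500 UMIs and 0.76 in the cluster rich in mitochondrial RNA, both outside that interval. All 636 alternative values of the 54 named gene results kept their direction, of which 574 stayed within the interval and 62 moved. These genes were picked for their extreme ratios in the same counts, so a kept direction says little about them. Of 1768 alternative values of 150 list medians, 1700 stayed within the interval or tolerance, 57 moved and 11 took the opposite sign where the interval lay on one side of 0. These intervals cover the spread between a list's genes and can be wide. That of the fetal and stress list in cardiomyocyte-like cells ran from 0.94 to 3.93. A sizeable shift can therefore count as within the interval. Of the 1700 and the 57, 81 and 11 also had the opposite sign, from intervals or tolerances that held 0. Of 47 alternative values of 6 class shares 13 moved and 1 took the opposite sign, of 8 for shares of cells with a UMI 2 did, and of 8 for library quality 1 did. For each value below the cause was not tested, unless it is stated.

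Shares, as log2 ratios, moved as follows. Cardiomyocyte-like cells went from -1.80 to -2.001 with a mitochondrial limit of 20%. Fibroblast-like cells went from -0.005 to -0.12 with at least 500 genes and 0.225 by marker scores. Vascular endothelial-like cells went from 0.15 to 0.29 with at least 500 genes and 0.29 with doublets kept. Endocardial-like cells went from 0.68 to 0.50 by marker scores. Macrophage-like cells went from 0.53 to 0.12 with at least 500 genes, 0.12 at resolution 2 and 0.20 by marker scores. As shares of cells that are not cardiomyocyte-like, where the total differs by construction, fibroblast-like cells were at -0.43, vascular endothelial-like at -0.27, of the opposite sign, endocardial-like at 0.255, macrophage-like at 0.104 and pericyte-like at -1.45. Shares of cells with a UMI went from 0.34 to 1.19 for Trp53 and from 1.43 to 2.07 for Cdkn1a without thinning, which keeps the depth difference. The ratio of median UMIs per cell went from 0.74 to 0.60 with at least 500 genes.

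List medians in cardiomyocyte-like cells depended most on the cluster rich in mitochondrial RNA. Without it, oxidative phosphorylation was -0.84, mitochondrially encoded genes -0.97, ribosomal proteins -0.55 and immediate early genes -0.11, all of the opposite sign. Fatty acid oxidation was then -0.94, glycolysis 0.22, the TCA cycle -0.44, oxidative stress defence -0.56, matrix 0.405, senescence 0.032, cardiomyocyte RNA -0.39 and blood RNA 1.48. In that cluster alone, oxidative phosphorylation was -0.15, mitochondrially encoded genes -0.003, ribosomal proteins 0.20 and nuclear RNA -0.52. With a mitochondrial limit of 20%, oxidative phosphorylation was -0.22, mitochondrially encoded genes -0.17, ribosomal proteins -0.023, the TCA cycle -0.185 and oxidative stress defence -0.14. Without cells that hold atrial genes, oxidative phosphorylation was 0.059 and ribosomal proteins 0.22. In cells of 500 to 1500 UMIs, oxidative phosphorylation was 0.036, mitochondrially encoded genes 0.10 and mitochondrial biogenesis 0.22. By marker scores, oxidative phosphorylation was 0.006, ribosomal proteins 0.205 and blood RNA 1.985. With the mean of per-cell CPM, oxidative phosphorylation was 0.33, the TCA cycle 0.27 and ribosomal proteins 0.575. Oxidative phosphorylation was 0.27 with at least 500 genes and 0.30 with median of ratios.

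In other classes blood RNA, a list of 5 genes, moved under several settings. In fibroblast-like cells it was 1.87 with at least 500 genes, 0.57 with a mitochondrial limit of 20%, 0.58 with none, 1.93 with doublets kept, 1.90 at resolution 0.5, 0.60 at resolution 2 and 1.575 by marker scores. In vascular endothelial-like cells it was 1.51, 1.81 and 1.52 under the first 3 of these, 1.54 at resolution 2, 1.43 by marker scores and 1.32 with the mean of per-cell CPM. It was 1.62 in endocardial-like cells by marker scores and 2.63 in macrophage-like cells with doublets kept. Mitochondrially encoded genes in fibroblast-like cells were -0.39 by marker scores. Oxidative phosphorylation in vascular endothelial-like cells was -0.997 at resolution 2, -0.96 by marker scores and -0.996 with median of ratios, and in endocardial-like cells -0.59 with the last. The monocyte-derived list in vascular endothelial-like cells was 4.06 by marker scores. Cell cycle G2M in endocardial-like cells was 0.24 with a mitochondrial limit of 20% and -1.19 by marker scores.

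In macrophage-like cells ribosomal proteins were -0.006 with at least 500 genes and -0.006 at resolution 2, both of the opposite sign, and 0.34 with a mitochondrial limit of 20%, 0.33 with doublets kept and 0.025 by marker scores. Endoplasmic reticulum stress was 0.22 with at least 500 genes and 0.46 with doublets kept, and immediate early genes 0.028 by marker scores. Cell cycle G2M was -0.048 by marker scores and -0.33 with members of at least 100 UMIs, and cell cycle S -0.51 with the latter, where fewer genes enter.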

Other observations

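Both tests named here were chosen after the result was seen.

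Mesothelial-like cells, which line the heart's surface, were 180 and 282 cells, and held more matrix and interferon response RNA in the library labelled p53 knockout. Of 35 measured matrix genes 30 were higher, with a median log2 ratio of 1.41 (percentile 100 of random lists), and of 22 interferon response genes 19 were higher, with a median of 0.74. Mesothelial-like cells held 219445 and 988719 nuclear-encoded UMIs, and their median over genes with at least 100 UMIs in a library was 0.12. In a library, 2 of these matrix and 3 of these interferon genes had 0 UMIs. Setting them to the 3-count floor left both medians as they were. The monocyte-derived macrophage list, which shares Fn1 and Thbs1 with the matrix list, had a median of 3.34 over 5 measured genes in the same cells. Hbb-bs, a haemoglobin gene, had 301 and 698 CPM there. The interferon list had a median of -0.79 in macrophage-like cells; the difference between the classes was not tested. Smooth muscle-like cells, 54 and 184, had 32 of 35 matrix genes higher, with a median of 2.35, or 1.99 with members that had 0 UMIs set to the 3-count floor. They held 50022 and 482768 nuclear-encoded UMIs, and their median over genes with at least 100 UMIs in a library was 0.40. Their cluster was itself led by genes that include Col1a1, Col11a1 and Thbs1, and 77.3% of it came from the library labelled p53 knockout. Pericyte-like cells had a median of 0.36 for the matrix list, with 24 of 31 genes higher.

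Proliferation RNA was sparse. After thinning to 500 UMIs, 0.217% and 0.441% of kept cells had a UMI of Mki67, a marker of cycling cells, against 0.318% and 1.02% without thinning. In cardiomyocyte-like cells, taken to lack it, the thinned shares were 0.105% and 0 of 865 cells, which allows up to 0.347%, at median depths of 995 and 1759 UMIs. In macrophage-like cells Mki67 had 23.2 and 60.9 CPM.

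Of 10554 genes with at least 20 UMIs in each of the 5 largest classes, 17 were at least 4-fold lower and 13 at least 4-fold higher in all 5 in the library labelled p53 knockout; these genes were chosen after their values were seen. The lower ones include Slc15a2 (199 and 6.32 CPM over all kept cells), Nmnat1 (95.6 and 10.3 CPM), Ces1d (146 and 22.1 CPM) and Ctla4 (67.9 and 7.07 CPM). Gabrb2, Tpm3-rs7 and Lrrtm3, given above class by class, are also among the lower ones. Nppa, Myl7, Spp1 and Ccn2 are among the higher ones. Of the 17, 4 lie on Y and 13 on neither X nor Y. Sex can change genes on any chromosome, and it cannot be told apart from genotype, since Xist differed by 8.60 on the log2 scale. A strain difference between the animals might also account for the 13, and cannot be told apart from genotype either because each genotype is 1 library. Of the 30 genes, 3 are on chromosome 11, the chromosome of Trp53, and 0 within 10 Mb of it.

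RNA of Gm42418 (3840 and 8111 CPM) and Cmss1 (2732 and 5739 CPM) over all kept cells was higher in the library labelled p53 knockout. So was that of Cdk8 (514 and 1247 CPM), Camk1d (503 and 1479 CPM) and Lars2 (96.0 and 287 CPM), while Gphn had 677 and 702 CPM. Over 10 classes the log2 ratio of Gm42418 ran from 0.27 to 1.40, so the difference was not tied to 1 class. Its cause was not tested.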
